A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

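Messenger RNA levels of budding yeast were measured with 6 one-colour Affymetrix expression arrays. Each array took up total RNA from whole cells grown in rich YPD medium without treatment, labelled with biotin by a 3' in vitro transcription kit, per the labels' protocols. The labels place 2 arrays in each of 3 groups: wild type (WT), and mutants M1 and M8 of Tra1. The labels number the arrays of a group 1 and 2. Tra1 is a large scaffold protein shared by the SAGA and NuA4 histone acetyltransferase complexes, which activator proteins such as Gal4 contact. The series describes the mutants as defective in the interaction with Gal4, and the amino acid changes in M1 and M8 were not given in the sources used here. The labels call the samples duplicates without saying whether these came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

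The deposited values are log2 expression levels per probe set, and RMA and the oligo package are named in the submitters' processing notes without versions. The settings of background correction, normalization and summarisation were not given in the sources used here. The deposited table held 9275 probe sets on 6 arrays, no value was missing, and the array medians lay between 6.48 and 6.52, so the arrays had been scaled to each other before deposit. RMA gives no detection call, and no signal over background was used here. A scaling of this kind assumes that most genes keep their level, so a global shift of all messages would not be visible in these values. The number of arrays limits the precision.

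The platform's gene table gave 1 gene for 6504 probe sets, several genes for 328 and no gene for 2443, which are unnamed here. All 6504 were matched to the gene table of the R64 assembly by their gene identifier, and 0 symbols had to be updated. The table served only for names and gene lengths. For 315 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays was taken, which left 5656 genes. The 2771 probe sets with several genes or none stayed outside the comparisons.

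Group means were fitted to the log2 values of all 6 arrays with limma 3.58.1 in R 4.3.3, which left 3 residual degrees of freedom. Moderated statistics came from eBayes with default settings, and p-values are two-sided. They were adjusted by the Benjamini-Hochberg method over the 5656 genes, and an adjusted p under 0.05 was called. The comparisons were M1 minus WT, M8 minus WT, M8 minus M1, and the mean of M1 and M8 minus WT. About 283 genes are expected at an unadjusted p under 0.05 by chance in each.

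The 34 gene lists were fixed before the data were examined. They cover Gal4 targets, subunits of SAGA, NuA4 and Mediator, stress, metabolic and cell cycle genes, and markers of mating type, sporulation and strain background. Lists were tested with camera at its preset correlation of 0.01, which asks whether a list shifted relative to all other genes. The p-values were adjusted over the 34 lists of a comparison. Beside this test stand camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction. The estimated correlation rests on 3 residual degrees of freedom, so a call lost under it does not show that a list was unchanged. Members were also counted after adjustment over the list alone.

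The rule for named genes was fixed before the data were examined. For each mutant against WT it takes the 10 largest changes in each direction among called genes whose mutant arrays all lie on the same side of both WT arrays, and 5 for the other comparisons. Where fewer than 3 genes pass, it takes the 5 with the smallest p, given as values. TRA1, GAL4 and the Gal4 targets are always named, as are up to 4 called members of a list that passed, or 2 with the largest absolute change where none was called. Genes known to have a near-identical copy are named with that caution, given once. Exceptions, chosen after their values were seen, are LYS20, HSP26, HSC82, HSP12 where it stands in a list, and the genes of the closing observations.

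The calculation was tested on simulated arrays with the real genes, in which 200 genes carried known changes. For the simulated comparison of M1 with WT, 33.9% of genes changed 1.5-fold were called, 90.9% of those changed 2-fold, 99.2% of those changed 3-fold and 99.4% of those changed 4-fold, and 4.39% of calls were false. All 3 simulated groups had the same spread, while the M1 duplicates differed more (SD 0.349 against 0.198 for WT and 0.142 for M8). These shares therefore need not hold for the real M1, where 7 genes differed 2-fold or more and 0 were called. For the simulated comparison of M8 with WT, a list shifted by 0.40 passed in 100% of simulations and 0% of the unshifted lists passed. The simulated genes varied independently, so these figures do not cover lists whose members vary together. The correlation of the M1 and M8 changes was set beside 100 simulations of groups without changes that share the WT arrays and have the same spread.

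The alternatives were the replicate number as a block, each array left out, only the groups compared, removal of dim genes, all probe sets, all one-gene probe sets, median centring, quantile normalization, an intensity trend with robust shrinkage, an ordinary linear model and a minimum change of 1.5-fold. Where an array was left out, its lone partner was assumed to vary like the other groups. The filter on dim genes used the 20th percentile of all probe sets, a log2 level of 4.08, because the gene table used here marks no probe sets of another species. It left 5352 genes. Array weights and a block with the M1 numbers exchanged were added after the data were seen. Figures were drawn in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.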

Results

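Expression was profiled in wild-type yeast and in M1 and M8, which are mutants of the coactivator subunit Tra1 defective in the interaction with the transcription activator Gal4. The data comprised 6 arrays, 2 per group, and log2 levels of 5656 genes. The arrays correlated with Pearson's r between 0.988 and 0.998 across all probe sets. The spread of the difference between duplicates over genes was 0.198 for WT, 0.349 for M1 and 0.142 for M8 (SD, log2). M1 replicate 2 lay farthest from the mean of the other 5 arrays, with an SD of 0.303 against 0.139 to 0.194 for the others. Signals of 91 tRNA genes had a median of 0.58 above the other 5 arrays in M1 replicate 2 and of -0.49 in M1 replicate 1. Whether the 3' labelling measures tRNA abundance was not tested.

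**Figure D1:**
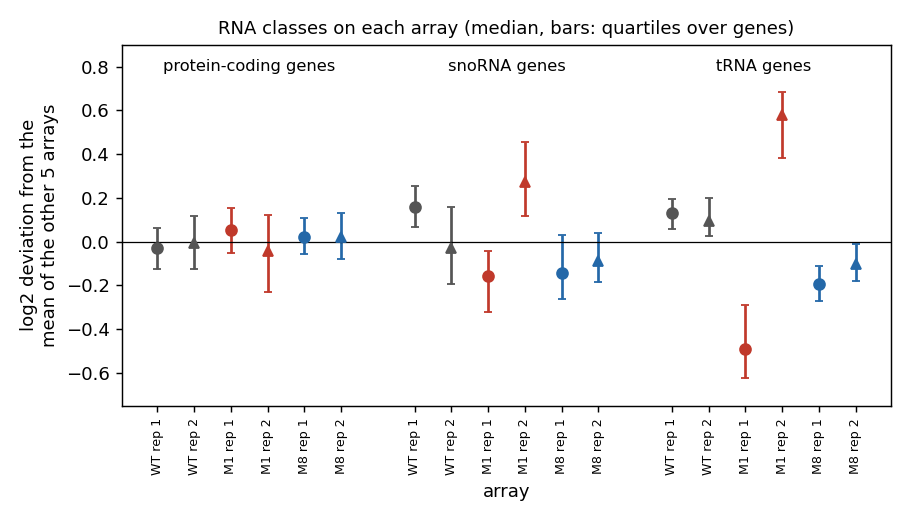
Median log2 deviation of each array (x axis) from the mean of the other 5 arrays (y axis), over protein-coding, snoRNA and tRNA genes, with bars spanning the quartiles over genes. The tRNA medians of the M1 arrays lie at -0.49 and 0.58, outside the range of -0.19 to 0.13 of the WT and M8 arrays.

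The first question was whether the mutants altered TRA1 itself, GAL4 or the genes that Gal4 activates, when no galactose was given. TRA1 (YHR099W) had log2 levels of 8.26 ± 0.21 in WT, 8.64 ± 0.21 in M1 and 8.72 ± 0.19 in M8 (SD, n = 2). The differences from WT were 0.38 (SE 0.17) and 0.46 (SE 0.17), with limma adjusted p = 0.599 and 0.660 after Benjamini-Hochberg correction. TRA1 is read by 13 probe sets, of which 11 were higher than WT in M1 and 12 in M8, with medians of 0.19 and 0.16. Whether the mutant allele is the only copy of TRA1 was not given in the sources used here, so these levels can stand for more than 1 copy. GAL4 differed from WT by 0.028 (SE 0.13) in M1 and 0.16 (SE 0.13) in M8.

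The 10 measured Gal4 targets showed no joint shift. Their medians were -0.10 in M1 and 0.0044 in M8, with camera adjusted p = 0.636 and 0.806. GCY1, a Gal4-regulated glycerol dehydrogenase gene, was the member with the largest difference, 0.49 (SE 0.11) in M1 and 0.41 (SE 0.11) in M8. Over all genes 0 members were called in either mutant by limma, with 1 higher and 0 lower at an unadjusted p under 0.05 in each mutant. GCY1 was the 1 member higher in M1 when adjusted over the list alone, and 0 were in M8. The structural galactose genes GAL1, GAL7 and GAL10, which are repressed in glucose, differed from WT by 0.18, -0.16 and -0.20 in M1 and by 0.15, -0.084 and -0.041 in M8. Their mean levels and that of GAL3 lay between percentiles 24.2 and 25.6 of all probe sets, and that of GAL4 at 28.3, so a further drop of these 5 genes was hardly detectable in this medium. The result for the list therefore rests mainly on its other 6 members. The permease gene GAL2 differed by 0.056 and 0.090, the sensor GAL3 by -0.019 and -0.0018, and GAL80, the inhibitor of Gal4, by -0.054 and 0.011. The sign of GAL80 in M8 turned under median centring and quantile normalization. FUR4 (-0.15 and -0.19), MTH1 (-0.15 and 0.16) and PCL10 (-0.20 and -0.0057) completed the list.

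**Figure D2:**
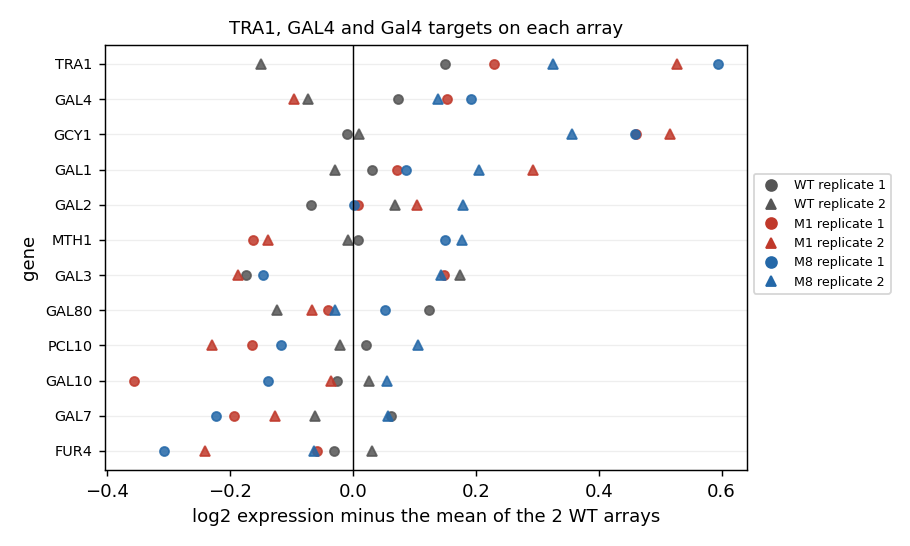
Log2 level of TRA1, GAL4 and the 10 measured Gal4 targets (y axis) on each of the 6 arrays, relative to the mean of the 2 WT arrays (x axis). Colours mark the groups and symbols the replicate number. GCY1 lies above both WT arrays on all 4 mutant arrays.

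In M1, genes of protein folding and of the general stress response were higher than in WT, as were amino acid biosynthesis genes, while mitotic genes and genes specific to MATa cells were lower. The heat shock chaperones, which are activated by Hsf1, rose as a list, with a median of 0.40 over 23 genes and camera adjusted p = 9.51e-12. Their call was lost with adjusted p = 0.270 with an estimated correlation, and fry gave an adjusted p = 0.0313. HSP82, an inducible Hsp90, was higher by 1.11 (SE 0.13) and HSP78, a mitochondrial disaggregase, by 0.85 (SE 0.13). Adjusted over the list alone, 14 chaperones were higher and 1 was lower, while 0 were called over all genes by limma, with 14 higher and 1 lower at an unadjusted p under 0.05. The lower gene was the small heat shock protein gene HSP26, with -0.37 (SE 0.14).

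The general stress genes activated by Msn2 and Msn4 rose in M1 with a median of 0.23 over 36 genes and camera adjusted p = 4.41e-05, a call lost with adjusted p = 0.588 with an estimated correlation. Adjusted over the list alone, 7 members were higher, among them the phosphoglucomutase gene PGM2 at 0.82 (SE 0.12), and 1 was lower, the cell wall protein gene SPI1 at -0.63 (SE 0.18). Amino acid biosynthesis genes rose with a median of 0.092 and adjusted p = 0.00145, or adjusted p = 0.588 with an estimated correlation. The median of the list was 0.19 without M1 replicate 2. Of its 38 members 3 were higher and 0 lower when adjusted over the list alone, all of them in lysine synthesis: LYS9 at 0.78 (SE 0.17), LYS1 at 0.59 (SE 0.13) and LYS20 at 0.54 (SE 0.13).

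Mitotic genes fell in M1, with a median of -0.31 over 10 genes and camera adjusted p = 6.98e-05, or adjusted p = 0.454 with an estimated correlation. The mitotic cyclin gene CLB1 was lower by -0.88 (SE 0.14) and passed when adjusted over the list alone, the only member to do so, and the transcription factor gene SWI5 differed by -0.58 (SE 0.20). The median of the list was -0.20 without WT replicate 2. The MATa-specific genes fell with a median of -0.40 over 7 genes and adjusted p = 7.17e-04, or adjusted p = 0.454 with an estimated correlation. Their median was -0.11 without M1 replicate 2, with adjusted p = 0.00646. Of these, 3 were lower and 0 higher when adjusted over the list alone, including the agglutinin gene AGA2 at -0.57 (SE 0.12) and the pheromone gene MFA1 at -0.52 (SE 0.15). A second probe set of MFA1 had -0.23. The histone list held only 4 measured genes, HHO1, HTB1, HTB2 and HTZ1. With all arrays a further 6 lists were lower by camera: ribosomal proteins (median -0.048), sulfur amino acids (-0.16), seripauperins and anaerobic mannoproteins (-0.11), histones (-0.23), multidrug resistance (-0.17) and purine synthesis (-0.16). Their adjusted p lay between 0.00378 and 0.0486, and between adjusted p = 0.588 and 0.785 with an estimated correlation. None of the 6 passed without M1 replicate 2, and the medians were -0.017 for ribosomal proteins, -0.11 for sulfur amino acids, 0.010 for seripauperins, -0.052 for histones, 0.012 for multidrug resistance and -0.048 for purine synthesis. Without M1 replicate 1 they were -0.078 for ribosomal proteins, -0.20 for seripauperins, -0.35 for multidrug resistance and -0.27 for purine synthesis. Without WT replicate 1 sulfur amino acids had -0.11, and without WT replicate 2 ribosomal proteins had -0.011 and histones -0.14. Their members with the largest differences included RPS28B (-0.76) and RPL13A (-0.51), whose probe sets can read a close copy. Others were MET6 (-0.70), MET13 (-0.48), TIR3 (-0.36), TIR2 (-0.33), HTB2 (-0.35), HTZ1 (-0.27), RSB1 (-0.60), TPO1 (-0.31), GCV1 (-0.59) and MTD1 (-0.36). Of these, RSB1 alone passed when adjusted over its list alone, and TPO1 turned to 0.011 without M1 replicate 2.

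Gene by gene, limma called 0 of 5656 genes in M1 after Benjamini-Hochberg correction, with 485 at an unadjusted p under 0.05 and 0 called by the ordinary linear model. The smallest adjusted p was 0.05004, just above the threshold, shared by NCE103, the carbonic anhydrase gene (1.14, SE 0.12), PDH1, a mitochondrial protein gene (1.31, SE 0.15), and the 5S ribosomal RNA gene RDN5-3 (1.195, SE 0.13). YAR068W differed by 0.76 (SE 0.11). RDN5-3, YAR068W, LYS20, HTB2, RPS27A and TPO2 have close copies whose transcripts their probe sets can also read. RDN5-3 encodes no message, and whether the 3' labelling measures its abundance was not tested. In the lower direction stood HSP30, a plasma membrane stress protein gene (-1.01, SE 0.13), COA2, a cytochrome oxidase assembly factor gene (-0.81, SE 0.13), IZH2, a zinc homeostasis gene (-0.64, SE 0.11), and YFL067W (-0.78, SE 0.14). The counts depended on M1 replicates that disagreed, and leaving out either of them brought genes past the threshold. Without M1 replicate 2 the larger falls included RNAs other than messages, such as RDN37-1 (-1.97), RDN18-1 (-1.24) and SNR46 (-0.89). M1 replicate 1, which then stood alone, had a tRNA median of -0.49. The number of lists passing was 11 with all arrays, 5 without M1 replicate 2 and 7 without WT replicate 1, and the heat shock, general stress, MATa and mitotic lists passed whichever array was left out. The amino acid list lost its call without M1 replicate 1.

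**Figure D3:**
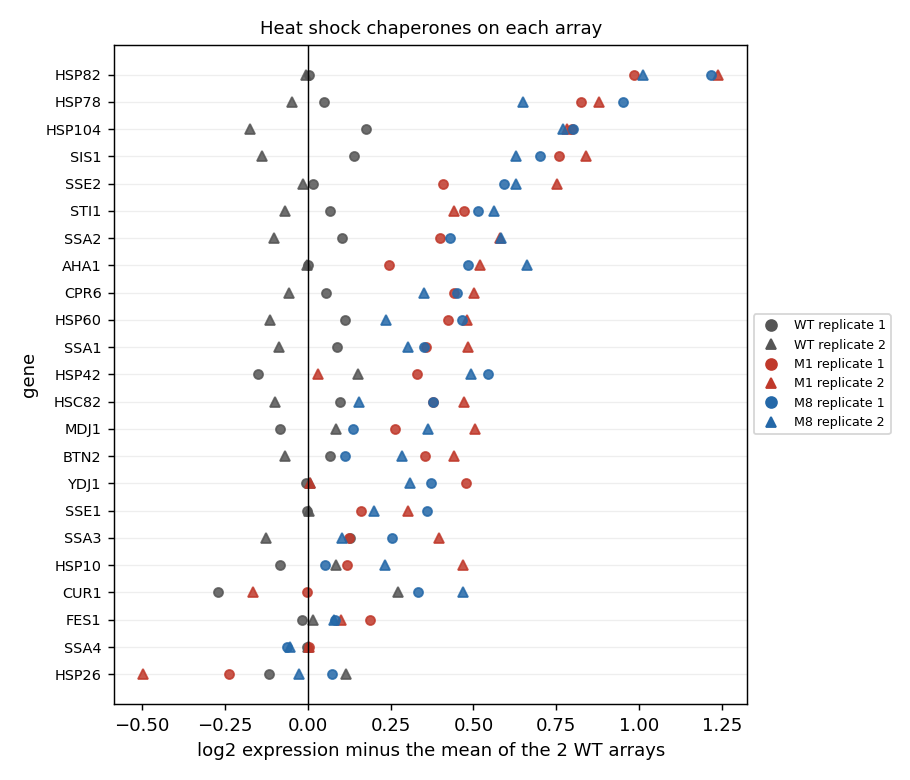
Log2 level of the 23 heat shock chaperone genes (y axis) on each of the 6 arrays, relative to the mean of the 2 WT arrays (x axis), ordered by the mean change of the mutants. For 17 of the 23 genes all 4 mutant arrays lie above both WT arrays.

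In M8, chaperone and general stress genes were again higher than in WT, together with iron uptake and proteasome genes, while ribosome biogenesis genes were lower. The heat shock chaperones rose with a median of 0.35 over 23 genes and camera adjusted p = 1.11e-13, a call lost with adjusted p = 0.173 with an estimated correlation. Tested by fry against no change, the list had an adjusted p = 0.0420. Adjusted over the list alone, 10 were higher and 0 lower, led by HSP82 at 1.11 (SE 0.13) and HSP78 at 0.80 (SE 0.13), and 0 were called over all genes by limma, with 13 higher and 0 lower at an unadjusted p under 0.05. The general stress genes rose with a median of 0.29 over 36 genes and adjusted p = 1.61e-08, or adjusted p = 0.390 with an estimated correlation. Adjusted over the list alone, 12 were higher and 1 was lower. The higher ones included the trehalose synthase subunit gene TSL1 at 0.82 (SE 0.15) and SOL4, a gene of the pentose phosphate pathway, at 0.78 (SE 0.13). The lower one was the membrane stress protein gene HSP12 at -0.44 (SE 0.12).

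The iron regulon, activated by Aft1, rose in M8 with a median of 0.14 over 16 genes and camera adjusted p = 0.0108, or adjusted p = 0.451 with an estimated correlation. TIS11, which encodes a protein that degrades messages under iron shortage, was higher by 0.70 (SE 0.11) and the cell wall mannoprotein gene FIT2 by 0.63 (SE 0.16), the 2 members that passed when adjusted over the list alone. Proteasome genes rose by a median of 0.13, with 31 of 33 above WT and camera adjusted p = 0.00729, or adjusted p = 0.728 with an estimated correlation. The list holds RPN4, the gene of a transcription factor, beside the subunit genes. The iron median was 0.25 without M8 replicate 2, and the proteasome median 0.057 without WT replicate 1 and 0.21 without WT replicate 2. RPN7 differed by 0.32 and PUP1 by 0.28, and 0 members passed when adjusted over the list alone. Amino acid biosynthesis genes rose by a median of 0.16 with adjusted p = 2.43e-04, or adjusted p = 0.549 with an estimated correlation. LYS9 differed by 0.67 (SE 0.17) and LYS1 by 0.55 (SE 0.13), and 0 members passed when adjusted over the list alone.

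Ribosome biogenesis genes fell in M8, with a median of -0.10, 47 of 62 below WT and camera adjusted p = 1.23e-05, or adjusted p = 0.173 with an estimated correlation. The snoRNP protein gene GAR1 differed by -0.40 (SE 0.17) and the RNA helicase gene DBP2 by -0.38 (SE 0.15), and 0 members passed when adjusted over the list alone. A second probe set of DBP2 had -0.14 in M8 and -0.57 in M1, so it was lower in M1 than in M8. Ribosomal protein genes fell with a median of -0.052 over 81 genes and adjusted p = 0.00164, or adjusted p = 0.728 with an estimated correlation. RPS26B differed by -0.51 and RPL7B, in the other direction, by 0.47, and both have a close copy. The median of the list was -0.088 without WT replicate 1. Phospholipid and fatty acid synthesis genes fell with a median of -0.14 and adjusted p = 0.00544, or adjusted p = 0.390 with an estimated correlation. OLE1, the fatty acid desaturase gene, differed by -0.53 (SE 0.15) and EKI1 by -0.28 (SE 0.13), and the median of the list was -0.086 without M8 replicate 1. The MATa-specific list passed in the lower direction with adjusted p = 0.0157, or adjusted p = 0.408 with an estimated correlation, although its median was -0.011. That median was -0.051 without WT replicate 1, -0.14 without WT replicate 2, -0.10 without M8 replicate 1 and -0.097 without M8 replicate 2. MFA1 at -0.59 (SE 0.15) and AGA2 at -0.52 (SE 0.12) were the 2 members lower when adjusted over the list alone. The second probe set of MFA1 had -0.37 in M8.

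Gene by gene, limma called 0 of 5656 genes in M8 after Benjamini-Hochberg correction, with 399 at an unadjusted p under 0.05 and 0 called by the ordinary linear model. The smallest adjusted p was 0.125, for PDH1 (1.23, SE 0.15) and HSP82. ALD6, the cytosolic acetaldehyde dehydrogenase gene, differed by 0.79 (SE 0.11), with -0.32 at a second, dim probe set, and AVT6, a vacuolar amino acid exporter gene, by 0.70 (SE 0.11). On the lower side stood HSP30 (-0.90, SE 0.13), the polyamine transporter gene TPO2 (-0.77, SE 0.12), IZH2 (-0.67, SE 0.11), the allantoin permease gene DAL4 (-0.65, SE 0.13) and the ethyl ester synthesis gene EEB1 (-0.57, SE 0.11). With the M1 arrays left out of the estimate of the spread, 23 genes were called in M8 (16 higher, 7 lower). Leaving out either M1 replicate is the same fit for this comparison, because a lone M1 array adds nothing to that estimate. Of the 9 lists passing, 5 passed without WT replicate 1, and these were the heat shock, general stress, amino acid, ribosomal protein and ribosome biogenesis lists. The ribosomal protein list lost its call without WT replicate 2.

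The mean of both mutants was set against WT, which gives the average change and can rest on 1 mutant alone. PDH1 (YPR002W) rose by 1.27 (SE 0.13), HSP82 (YPL240C) by 1.11 (SE 0.12) and NCE103 (YNL036W) by 0.91 (SE 0.10), with limma adjusted p = 0.0418 for each after Benjamini-Hochberg correction. HSP30 (YCR021C) fell by 0.95 (SE 0.11), with adjusted p = 0.0479. PDH1 had log2 levels of 6.68 ± 0.12 in WT, 7.99 ± 0.24 in M1 and 7.91 ± 0.10 in M8, and HSP82 of 9.04 ± 0.01, 10.15 ± 0.18 and 10.15 ± 0.15 (SD, n = 2). HSP82 has a near-identical copy, HSC82, which differed by 0.35 (SE 0.11). These 4 genes, 3 higher and 1 lower, were all that limma called, against 452 at an unadjusted p under 0.05 and 0 by the ordinary linear model. None of the 4 was called when all one-gene probe sets entered the adjustment. The smallest p among the other lower genes belonged to IZH2 at -0.65 (SE 0.094, adjusted p = 0.101), COA2 at -0.64 (SE 0.11), YFL067W at -0.67 (SE 0.12) and YDR034C-A at -1.15 (SE 0.20), the last 3 with adjusted p = 0.157. The 6 other probe sets of YDR034C-A do not show that drop, with -0.032 to 0.44 in M1 and -0.37 to 0.045 in M8. TRA1 differed by 0.42 (SE 0.14, adjusted p = 0.515) and GCY1 by 0.45 (SE 0.095, adjusted p = 0.236).

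Among the lists, 11 passed for the mean of the mutants, 3 higher and 8 lower. The heat shock list had a median of 0.35, with adjusted p = 4.65e-15, or adjusted p = 0.189 with an estimated correlation, and fry gave an adjusted p = 0.0241. Of its 23 members 17 had all 4 mutant arrays above both WT arrays, against 11.9% of all genes and 6.67% by chance. Over all genes 1 member was called higher, HSP82, and adjusted over the list alone 14 were higher and 0 lower. General stress genes had a median of 0.26, with adjusted p = 6.13e-08, or adjusted p = 0.357 with an estimated correlation. Over all genes 0 of them were called by limma, with 17 higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 12 were higher, led by PGM2 (0.73) and TSL1 (0.70), and 1 was lower. The amino acid list (median 0.11, adjusted p = 1.32e-04) lost its call with adjusted p = 0.498 with an estimated correlation. The other 8 were the ribosomal protein, ribosome biogenesis, sulfur amino acid, MATa-specific, seripauperin, phospholipid, mitotic and purine lists, with medians between -0.21 and -0.040 and adjusted p between 9.54e-04 and 0.0421, and between adjusted p = 0.357 and 0.734 with an estimated correlation. Of these, ribosome biogenesis had a median of 0.038 in M1, and mitotic and purine genes had -0.045 and -0.011 in M8, so their shift lies mainly in the other mutant. The leading members of the 8 lists were RPS27A (-0.47), DBP2 (-0.34), MET6 (-0.48), MFA1 (-0.56), TIR3 (-0.25), OLE1 (-0.44), CLB1 (-0.54) and GCV1 (-0.30). The count of 4 genes became 132 without M1 replicate 2 and 51 without M1 replicate 1, each including the 4, and 0 without any of the WT or M8 arrays. The count of 11 lists became 4 without WT replicate 1: heat shock, general stress, amino acid and ribosomal protein. The last of these lost its call without WT replicate 2. The medians of the heat shock and general stress lists stayed within a factor of 1.5 whichever array was left out. Without M1 replicate 2 the medians were -0.036 for ribosomal proteins, -0.071 for sulfur amino acids, -0.041 for MATa-specific genes, -0.022 for seripauperins and -0.013 for purine synthesis. Without M1 replicate 1 they were 0.063 for amino acids, -0.36 for MATa-specific genes, -0.13 for seripauperins, -0.18 for mitotic genes and -0.13 for purine synthesis. Without WT replicate 1 sulfur amino acids had -0.075 and mitotic genes -0.18, and without WT replicate 2 ribosomal proteins had -0.018 and ribosome biogenesis -0.016.

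The changes of M1 and M8 correlated with Pearson's r of 0.481 and Spearman's rho of 0.426 across the 5656 genes, which are not independent replicates. Simulated groups without changes that share the WT arrays gave a Pearson's r of 0.50. The same sign was taken by 65.3% of genes, under the simulated mean of 66.7% and the lowest simulated value of 65.5%. All simulated groups had the same spread, while the SD between duplicates was 0.198 for WT, 0.349 for M1 and 0.142 for M8. The simulated values therefore need not hold here, and agreement under that of shared controls cannot be read from them. The covariance was 0.0178 against 0.0117 in the simulations. It was 0.0278 without M1 replicate 2, 0.00770 without M1 replicate 1 and 0.0339 without WT replicate 1. The WT duplicates gave a variance of the WT mean of 0.00995, the part that shared controls add. Without M1 replicate 1 the covariance lay under this value, so no excess was left. A lone WT array adds more shared variance, so the value without WT replicate 1 has no like benchmark here. At an unadjusted p under 0.05, 110 genes were higher in both mutants, against 31.9 in the simulations and 13.7 for independent lists, and 55 were lower in both, against 31.7 and 4.54. Opposite directions were taken by 0 genes, against 1.12 in the simulations, with 289 higher and 196 lower in M1 and 268 and 131 in M8. With 2 WT arrays the controls could not be divided into parts of at least 2, so part of the excess in covariance and shared genes may come from the shared controls.

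**Figure D4:**
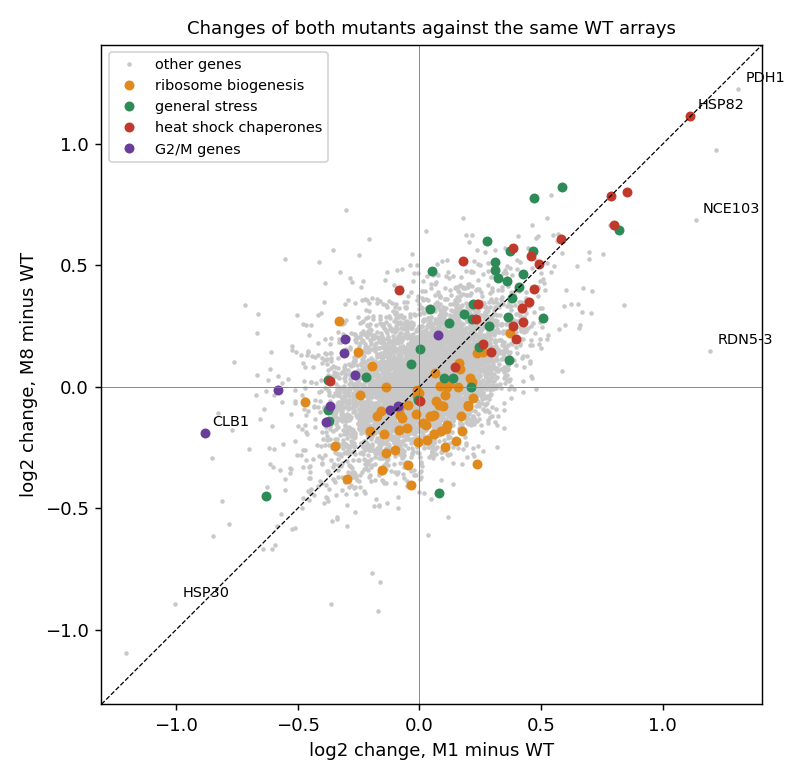
Log2 change of each gene in M1 (x axis) and M8 (y axis) against the same 2 WT arrays, with 4 gene lists in colour and the line of equal change dashed. HSP82 lies on the line at 1.11 in both mutants, while RDN5-3 lies at 1.195 in M1 and 0.15 in M8 and CLB1 at -0.88 and -0.19.

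The direct comparison of M8 with M1 asked where the mutants differ. Mitotic genes were higher in M8, with a median of 0.30, all 10 measured members above M1 and camera adjusted p = 1.83e-04, or adjusted p = 0.728 with an estimated correlation. CLB1 differed by 0.69 (SE 0.14) and was the 1 member higher when adjusted over the list alone, and SWI5 differed by 0.57 (SE 0.20). Ribosome biogenesis genes were lower in M8, with a median of -0.13, 52 of 62 below M1 and adjusted p = 4.57e-05, or adjusted p = 0.354 with an estimated correlation. SSF1, an assembly factor gene, differed by -0.55 (SE 0.20) and IMP3, in the other direction, by 0.60 (SE 0.30). The other 7 lists were higher in M8: TCA cycle and respiration (0.083), iron (0.15), cell wall integrity (0.19), histones (0.28), multidrug resistance (0.16), proteasome (0.14) and purine synthesis (0.18). Their adjusted p lay between 0.0260 and 0.0358, and between adjusted p = 0.751 and 0.803 with an estimated correlation. TIS11 (0.52, SE 0.11) in the iron list and GCV1 (0.59, SE 0.16) and MTD1 (0.50, SE 0.12) in the purine list were higher when adjusted over the list alone, and 0 members of the other 5 passed. The members with the largest differences included RIP1 (1.08, SE 0.49), SDH2 (0.72), FIT3 (0.55), PIR3 (0.96), PIR1 (0.65), HTB2 (0.39), SNQ2 (0.45), RSB1 (0.34), PRE1 (0.51) and PRE4 (0.45).

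Between the mutants limma called 0 genes after Benjamini-Hochberg correction, with 364 at an unadjusted p under 0.05 and 0 called by the ordinary linear model. RDN5-3 had the smallest adjusted p, 0.289, at -1.05 (SE 0.13). The phosphate regulator gene PHO4 differed by 0.80 (SE 0.19), YKR041W by 0.56 (SE 0.12), TPO2 by -0.57 (SE 0.12), HSP12 by -0.52 (SE 0.12), AST1 by -0.44 (SE 0.11) and FAL1 by -0.45 (SE 0.11). The other probe set of AST1 had 0.12, in the opposite direction. TRA1 differed by 0.081 (SE 0.17) and the Gal4 targets by a median of 0.049, with camera adjusted p = 0.502. Without M1 replicate 2, 7 genes were called and 2 of the 9 lists passed, mitotic and ribosome biogenesis genes, and without M1 replicate 1, 748 genes were called and 6 lists passed. Without M8 replicate 1, 4 lists passed. The medians of the other 7 without M1 replicate 2 were 0.039 for the TCA cycle, 0.056 for iron, -0.078 for cell wall integrity, 0.15 for histones, 0.0071 for multidrug resistance, 0.059 for the proteasome and 0.11 for purine synthesis. Without M1 replicate 1 they were 0.23 for the TCA cycle, 0.56 for cell wall integrity, 0.43 for histones, 0.29 for multidrug resistance and 0.29 for purine synthesis. Without M8 replicate 2 mitotic genes had 0.20 and iron 0.24.

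With all arrays the remaining lists did not pass in any comparison, among them the subunits of SAGA, with medians of 0.0011 in M1 and 0.0036 in M8, of NuA4 (0.038 and 0.017) and of Mediator (-0.012 and 0.044). The assembly factors of Tra1, which include HSP82, came closest in M1, with a median of 0.067 and camera adjusted p = 0.0505. They passed without either M8 array, with adjusted p = 0.0425, and without M1 replicate 2 their median was 0.21 with adjusted p = 0.10035. Among other markers that did not pass, MATalpha-specific genes had medians of -0.17 and -0.017, sporulation genes of 0.029 and -0.016, and auxotrophic markers of -0.049 and 0.070. Sporulation genes passed between the mutants without M8 replicate 2, with a median of -0.13 and adjusted p = 0.0130. The medians for the others were 0.029 and 0.13 for the PHO regulon, 0.013 and 0.028 for glycolysis, 0.034 and 0.12 for glucose-repressed carbon genes, -0.052 and -0.0023 for hexose transporters, and -0.026 and -0.015 for pheromone response genes. They were -0.045 and 0.091 for COS genes, 0.015 and 0.0077 for sterol biosynthesis, 0.051 and 0.043 for G1/S genes, and 0.085 and 0.058 for DNA damage genes. The PHO regulon passed for the mean of the mutants without M1 replicate 2, with adjusted p = 0.0420 and a median of 0.19 against 0.066 with all arrays, and its median in M1 was then 0.21. Other lists gained a call lower than WT with 1 array left out. In M1 these were phospholipid synthesis without WT replicate 2 (adjusted p = 0.0251), and without M1 replicate 1 TCA cycle (0.0164) and cell wall genes (1.66e-04). In the mean these were cell wall (0.00658) and multidrug resistance genes (0.0158) without M1 replicate 1, while the proteasome was higher without WT replicate 2 (0.00129). The sign of median, mean and test differed for 2 lists in M1, 5 in M8, 5 between the mutants and 8 for their mean, none of which passed.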

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

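The tests in this part were chosen after the values they concern had been seen. The lists that differed between M8 and M1 by a test of the difference itself are given first, as median log2 differences of M8 minus M1. Mitotic genes were at 0.30 and ribosome biogenesis genes at -0.13. Without M1 replicate 2 these medians were 0.26 and -0.14 and still passed camera, with adjusted p = 9.87e-04 and 4.81e-05, and without M1 replicate 1 they were 0.299 and -0.099, with adjusted p = 0.0212 and 0.0165. Neither M1 array alone is therefore their source. Against WT the mitotic shift lay mainly in M1 (-0.31) and the ribosome biogenesis shift mainly in M8 (-0.10). A condition shared by both arrays of M1, or by both of M8, and the genotype stay open. The estimated correlation leaves neither list with a call. The other 7 were TCA cycle and respiration (0.083), iron (0.15), cell wall integrity (0.19), histones (0.28), multidrug resistance (0.16), proteasome (0.14) and purine synthesis (0.18). Without M1 replicate 2 the middle one of their medians went from 0.16 to 0.056, 0 of them passed and cell wall integrity turned to -0.078, in line with M1 replicate 2 as the source for the set as a whole. Histones (0.15) and purine synthesis (0.11) lost their calls but kept more than 50% of their medians, so their source stays open.

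The M1 arrays lay apart from each other. The tRNA medians were 0.58 in M1 replicate 2 and -0.49 in M1 replicate 1, RDN37-1, the ribosomal RNA precursor gene, was at 13.5 and 10.8 against 12.8 on both WT arrays, and RDN18-1 at 11.3 and 8.86. Other ribosomal RNA genes differed less between M1 replicates 2 and 1. In that order RDN25-1 was at 13.9 and 13.6, RDN5-1 at 12.3 and 11.8, and RDN5-3 at 9.28 and 9.24. A trend with gene length is argued against by a Spearman correlation across protein-coding genes of 0.0700 between the deviation of M1 replicate 2 and gene length. With the mean level the correlation was -0.0741. The lower quartiles of the arrays lay between 4.44 and 4.52 and the upper ones between 8.20 and 8.22. Scaling before deposit can thus have removed a trend with brightness, so this value does not decide on one. Labelling, RNA quality, a difference between cultures and the normalization were not tested and may each contribute, and no biological explanation was tested.

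The stress genes that were higher in both mutants are the third pattern. A single array is argued against: over the 8 pairs of 1 mutant and 1 WT array the median of the heat shock list had a lowest value of 0.297, and that of the general stress list of 0.117. Signal shared by near-identical paralogs is argued against, since 11 members with no close paralog had a median of 0.35 in the mean of the mutants. An effect of the WT culture cannot be told apart from the Tra1 mutations, because the same 2 WT arrays serve both comparisons: M8 minus M1 was -0.051 for the list, and the WT arrays differed by 0.030. Independent WT cultures would be needed.

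Among the probe sets with no single gene name, which the comparisons did not use, 1 was above WT in a fit of that class alone: it was higher in the mean of the mutants by 1.56 (SE 0.15, limma adjusted p = 0.0359 after Benjamini-Hochberg correction). Adjusted over all probe sets it was not called, with adjusted p = 0.0638. It was at 8.16 and 8.36 on the WT arrays and between 9.61 and 9.99 on the mutant arrays.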

How the results depend on the processing

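Array weights and the block with exchanged M1 numbers were chosen after the data were seen, the other settings before. The cause of the changes below was not tested. HSP82, PDH1, NCE103 and HSP30 were the 4 genes called in the mean of the mutants. The count was 0 with the replicate number as a block, and the replicate deviations correlated at -0.306 between WT and M1, 0.297 between WT and M8 and -0.111 between M1 and M8, which differ in sign. With the M1 numbers exchanged all 3 would be positive, and the count under that block was 4. It was 0 with all one-gene probe sets and with the ordinary linear model, 1 with all probe sets (an unnamed probe set, none of the 4 genes), 16 with array weights, and from 0 to 132 with 1 array left out. For M1 the count was 3 with an intensity trend and robust shrinkage, 2 with array weights, 5 with exchanged M1 numbers, and from 0 to 382 with 1 array left out. For M8 it was 23 with only the groups compared, 56 with array weights and from 0 to 23 with 1 array left out, and between the mutants from 0 to 748.

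The heat shock list had adjusted p = 0.270 in M1, 0.173 in M8 and 0.189 in the mean with an estimated correlation, and the general stress list 0.588, 0.390 and 0.357, with 0.141, 0.122 and 0.128 by fry. With 1 array left out the adjusted p of the heat shock list stayed between 2.36e-12 and 3.57e-06 in M1, 2.96e-14 and 1.04e-10 in M8, and 3.75e-16 and 5.63e-09 in the mean. The lists passing numbered 0 in all 4 comparisons with an estimated correlation, and by fry 1 in M1, 1 in M8, 0 between the mutants and 1 in the mean. With 1 array left out they ranged from 5 to 12 in M1, 5 to 9 in M8, 2 to 9 between the mutants and 4 to 12 in the mean. The covariance of the mutants' changes ranged from 0.00770 to 0.0339, and was 0.0278 without M1 replicate 2.

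The sign turned for some genes that were not called, given here as the lowest and highest log2 change with 1 array left out. In M1 these were GAL4 (-0.097 to 0.15), GAL2 (-0.013 to 0.12), GAL3 (-0.19 to 0.15), GAL80 (-0.18 to 0.070) and TPO1 (-0.63 to 0.011). In M8 they were GAL10 (-0.14 to 0.056), GAL7 (-0.22 to 0.056), GAL3 (-0.18 to 0.17), PCL10 (-0.12 to 0.11) and GAL80 (-0.11 to 0.13, with -0.018 under median centring and -0.0044 under quantile normalization). Between the mutants they were TRA1 (-0.067 to 0.23), FUR4 (-0.16 to 0.086), GAL1 (-0.15 to 0.073), GAL10 (-0.0043 to 0.32), GAL7 (-0.063 to 0.22), GAL2 (-0.055 to 0.12) and GAL3 (-0.15 to 0.19), with -0.0067 for GAL2 and -0.027 for GAL3 under quantile normalization. In the mean they were GAL3 (-0.18 to 0.16), GAL80 (-0.15 to 0.10) and MTH1 (-9.6e-04 to 0.014, with -0.015 under median centring and -0.014 under quantile normalization). The cell wall list turned between the mutants without M1 replicate 2, with adjusted p = 0.732 there and from 7.37e-05 to that value over the arrays left out.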

Other observations

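The test on retrograde genes below was written before its result was computed, but its genes come from the same arrays as those that prompted it. Without M1 replicate 2, an alternative in which the lone M1 array was assumed to vary like the others, the genes called higher in M8 included RDS1 (0.98, SE 0.097), IDH1 (0.67, SE 0.089) and ALD4 (0.62, SE 0.093). The named genes here were chosen after their values were seen. In the main comparison ALD4, the mitochondrial aldehyde dehydrogenase gene, was higher by 0.49 in M1 and 0.62 in M8 when adjusted over the list of glucose-repressed carbon genes alone. PCK1, a gluconeogenesis gene, was higher by 0.71 (SE 0.14) in M1 in the same way, while the list as a whole did not pass. MAG1, a DNA repair gene, was the 1 member higher in the DNA damage list adjusted over the list alone in the mean of the mutants, by 0.39 (SE 0.097).

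Several genes of the retrograde response, which signals mitochondrial state to the nucleus and feeds glutamate and lysine synthesis, stood among the larger values of the mutants: CIT2 (0.59, SE 0.10), DLD3 (0.63, SE 0.11), PYC1 (0.55, SE 0.12) and IDH1 (0.57, SE 0.11) in the mean of the mutants against WT. None passed over all genes, with limma adjusted p between 0.157 and 0.278 after Benjamini-Hochberg correction. The hypothesis that genes of this response were higher together was tested on 3 further members. The alternative without M1 replicate 2 also held them among the higher genes in the mean: ACO1 (0.57), CIT1 (0.61) and IDH2 (0.57). The test is therefore not independent of the values that prompted it. ACO1 differed by 0.50 (SE 0.13), CIT1 by 0.50 (SE 0.14) and IDH2 by 0.40 (SE 0.17), and their median of 0.50 lay at the 99.95th percentile of 10000 random lists of 3 genes matched on mean level. None of the 3 passed over all genes, with adjusted p = 0.344, 0.380 and 0.616. Random lists treat genes as independent, while these are regulated together, so the percentile can overstate the evidence. The TCA cycle and respiration list that holds all 3 had a median of 0.015, with 23 genes higher and 21 lower. That list also holds respiratory chain genes, so its median does not decide the question. The hypothesis therefore stays open, and a shift of the WT culture could give the same value.

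On the lower side, single probe sets with no gene name held large differences. Of the 2771 probe sets outside the comparisons, 127 had an unadjusted limma p under 0.05 in the mean of the mutants, against 452 of the 5656 genes. In a fit of the 2771 unnamed or ambiguous probe sets, 1 was lower in the mean of the mutants by -1.49 (SE 0.12) and another by -0.999 (SE 0.10), with limma adjusted p = 0.0194 and 0.0399 after Benjamini-Hochberg correction. Adjusted over all probe sets these were 0.0300 and 0.0647, so only the first was called there. The levels of the first were 10.5 and 10.4 on the WT arrays and between 8.89 and 9.13 on the mutant arrays.

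The M1 arrays also differed for single protein-coding genes. PUF3, which encodes an RNA-binding protein, was at 6.15 in M1 replicate 1 and between 4.63 and 5.11 on the other 5 arrays, and MPT5, a gene of the same family, was at 7.44 there, 9.22 in M1 replicate 2 and between 8.26 and 8.53 on the other 4. The difference of M1 replicate 2 minus 1 correlated across genes with that of WT replicate 1 minus 2, with Pearson's r of 0.306 and Spearman's rho of 0.281.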
